A study of Mus musculus with 22 samples.

How the data were processed

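Total RNA was extracted with TRIzol from mouse hearts or isolated ventricles at embryonic day E13.5, and libraries were made with a stranded mRNA kit and sequenced on an Illumina HiSeq 4000, per the labels' protocols. RNA integrity numbers are given there as 6.1 to 10. The series describes its hearts as coming from Prdm16 conditional knockout (cKO) mice and littermate controls, and the labels give 6 groups of libraries: 3 per genotype for the whole heart, and 4 per genotype for each of the left and the right ventricle.

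Each of the 22 deposited files holds estimated counts of reads and TPM (abundance relative to length and library) for 140658 transcripts, made with Salmon 1.2.1 per the submitters' processing notes. These notes also name DESeq2 1.22.2 and the genome builds GRCm38.p6 and mm10. The deposited estimated counts were neither log-transformed nor scaled between libraries, as their non-whole values and differing totals show, and the deposited TPM are scaled to transcript length and library. Transcripts were matched by their identifier without version to GENCODE M21 (GRCm38), in which 140137 were found. The other 521 held at most 0.204% of a library's reads and were left out. Estimated counts were summed to 54356 genes and rounded, and TPM were summed per gene.

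Gene tests used edgeR 4.0.16 (quasi-likelihood F test, TMM factors, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. The 6 whole heart libraries were fitted alone (19160 genes) and the 16 ventricle libraries in one model with 4 group means (16448 genes). The comparisons were cKO against control in each of the 3 tissues, the difference between the left and right ventricle in that effect, and left against right ventricle within each genotype. Fold changes are log2, cKO over control or left over right. The SE is the absolute log2 fold change divided by the root of the F statistic. The libraries were treated as separate animals within a tissue. The series counts its hearts and ventricles in pairs of cKO and littermate control, but no label says which libraries form a pair, or whether a left and a right ventricle came from the same heart. No block was used in the tests reported.

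In total, 34 gene lists, written before the data were examined, were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated correlation, on log2 CPM with a prior count of 2. Adjusted p values for lists are over the 34 lists. Counts of list members called are over all genes tested unless given as adjusted over the list alone. Some lists are given by their median alone, and some are not described.

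Genes were named by a rule set at the same time as the lists. It takes Prdm16, 14 cardiac genes, up to 4 members of each list with the smallest p, and the 10 largest changes in each direction (5 for the comparisons between ventricles). The largest changes were taken among called protein-coding genes with a mean of at least 2 log2 CPM and, except for the difference between ventricles, no overlap between the libraries of the 2 groups. Xist, Y-linked genes, haemoglobin genes and clone-like names were not eligible. Some genes that the rule takes are not reported here.

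The tests were checked on counts simulated from the real means, library sizes and dispersions. Among genes with a mean of at least 1 CPM, 100 were changed by 1 and 100 by 0.5 on the log2 scale. In the whole heart design 80% and 40% of these were called among 18520 genes, in the left ventricle 89% and 69% among 16249, in the right ventricle 83% and 65% among 16260, and for the difference between ventricles 80% and 52% among 16249. For left against right, 93% and 59% were called in the control design and 91% and 63% in the cKO design, among 16233 genes. Of unchanged genes, 0.02% to 0.08% were called.

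Ventricle-enriched genes were defined from controls 1 and 2 and tested in the cKO against controls 3 and 4, so that no control entered both steps. Alternatives covered the scaling (RLE factors, library totals, haemoglobin genes left out), the filter on low counts (none, or at least 1 CPM), the test (DESeq2 1.42.0, limma voom with quality weights, robust dispersion), length-scaled counts, the libraries fitted together, a replicate block, a fold change threshold and leaving out each library. A term for sex was not run, since the libraries all had high Xist and low Y-linked expression. The deposited transcript-level estimates of Prdm16 are not reported here, because the split of reads between its isoforms varied within groups.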

Results

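RNA from mouse hearts at embryonic day E13.5 was measured by bulk RNA sequencing in 22 libraries. Hearts with a conditional knockout of Prdm16 (cKO) were set against hearts of littermate controls, as 3 and 3 whole hearts, 4 and 4 isolated left ventricles and 4 and 4 isolated right ventricles. Prdm16 encodes a zinc finger transcription factor with a PR domain. Whole heart libraries held 38590751 to 62004017 reads assigned to transcripts and ventricle libraries 14508722 to 22830716. The spread between replicates, as the biological coefficient of variation, was 0.184 in the whole hearts and 0.0929 in the ventricles. It was 0.107 in the whole hearts without control 1, and 0.0735 in the ventricles without right ventricle control 2, both described below. All 22 libraries had Xist at 113.26 to 273.57 TPM and the Y-linked genes at 0.52 to 2.41 TPM in sum. Whole heart control 1 stood apart from the other 5 whole hearts, with 18966 genes detected at a common depth of 14486402 reads against 22483 to 23519 in the other 21 libraries. Right ventricle control 2 stood apart from the other 3 right ventricle controls, with Postn at 266 TPM against 44.6 ± 2.83 (SD) and Meox1 at 25.8 TPM against 1.71 ± 0.233. Lead counts of the comparisons that these libraries enter are therefore also given without them. The left ventricle comparison and left against right in the cKO share a fit with right ventricle control 2. Their counts were not computed without it.

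Prdm16 (ENSMUSG00000039410.16, chromosome 4, 154316125 to 154636873 on the minus strand, GRCm38) was lower in CPM in each cKO library than in each control library of the same tissue. In TPM, left ventricle cKO 1 (5.75) lay above left ventricle control 1 (5.37). In the whole heart the cKO libraries had 20.62, 19 and 22.28 CPM and the controls 45.29, 45.02 and 37.38 CPM. In the left ventricle the cKO libraries had 23.36, 21.56, 21.96 and 22.18 CPM and the controls 45.42, 53.88, 47.61 and 56.18 CPM. In the right ventricle the cKO libraries had 25.78, 23.11, 22.84 and 22.2 CPM and the controls 38.69, 37.49, 38.04 and 44.31 CPM. The log2 fold change of Prdm16 was -1.04 in the whole heart (SE 0.09, adjusted p = 0.00192), -1.19 in the left ventricle (SE 0.07, adjusted p = 6.47e-09) and -0.75 in the right ventricle (SE 0.07, adjusted p = 2.96e-06). The deposited TPM were tested with limma as log2 of TPM plus 1, where the added 1 makes differences smaller at these levels. The differences for Prdm16 were -0.824 (adjusted p = 0.139), -0.675 (adjusted p = 0.00829) and -0.5 (adjusted p = 0.0984) in that order. The calls in the whole heart and right ventricle were thus lost on that scale. In the controls Prdm16 was higher in the left than in the right ventricle (log2 0.36, adjusted p = 0.00131), whereas the cKO ventricles had a difference of -0.08 (adjusted p = 0.459). Counts per gene include reads from each exon, deleted or not, and from cells without the deletion, so the remaining level does not measure how complete the deletion was.

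**Figure D1:**
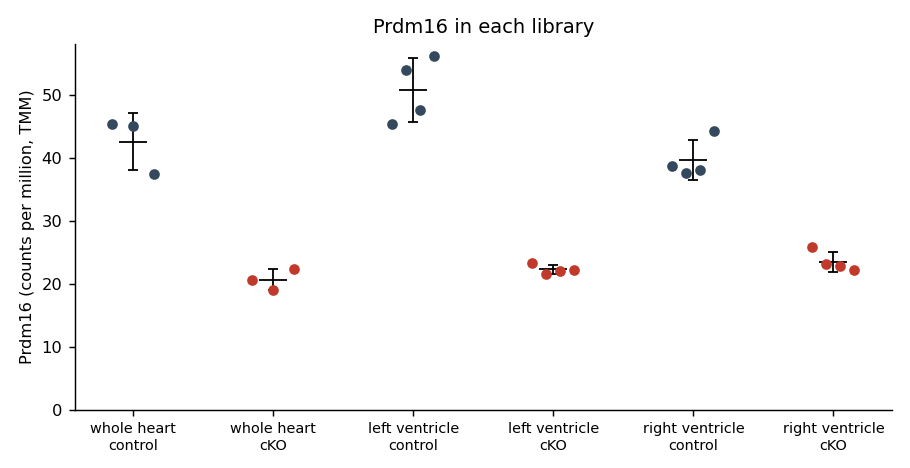
Prdm16 level in CPM (vertical axis) of each library (dots), with the mean and SD of each group (bars), for control and cKO whole hearts, left ventricles and right ventricles. The 8 cKO ventricle libraries lie between 21.56 and 25.78 CPM and the 8 control ventricle libraries between 37.49 and 56.18 CPM.

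The left ventricle comparison asked which genes depend on Prdm16 there. In left ventricles of the cKO, Hey2 and Mycn, regulators of the compact ventricular wall, were lower, and Tbx5 and Nppa were higher. Most of the fixed lists' genes for oxidative phosphorylation, fatty acid oxidation and ventricular cardiomyocytes were lower, and 7 of 13 atrial cardiomyocyte markers were higher. These list calls were lost with an estimated correlation (adjusted p = 0.243, 0.173, 0.203 and 0.0794). Of 16448 genes tested, 4216 differed (25.6%), 2017 of them higher and 2199 lower, and 400 changed by more than 1 on the log2 scale (255 higher, 145 lower). Length-scaled counts gave 2683 genes, and library totals 2211 higher and 1991 lower.

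Hey2 (ENSMUSG00000019789.9, chromosome 10, 30832359 to 30842801), which encodes a transcriptional repressor of the compact ventricular wall, fell 2.21-fold, from 58.4 ± 0.987 to 27.2 ± 2.91 TPM (SD, 4 libraries each; log2 fold change -1.14, SE 0.06, adjusted p = 1.45e-09). Mycn (chromosome 12, 12936093 to 12941914), a growth regulator of the compact myocardium, fell from 17.2 ± 1.35 to 10.6 ± 0.819 TPM (log2 fold change -0.81, adjusted p = 2.73e-08). The ventricular light chain gene Myl2 fell from 27600 ± 1150 to 21000 ± 2730 TPM (log2 fold change -0.52, adjusted p = 1.20e-04), and Myh7 (-0.41), Irx4 (-0.50) and Irx3 (-0.42) also fell. Of 9 ventricular cardiomyocyte markers, 7 were lower and 0 higher (7 lower and 1 higher adjusted over the list alone; median log2 fold change -0.50; camera adjusted p = 1.01e-04, and adjusted p = 0.203 with an estimated correlation). Of 13 atrial cardiomyocyte markers, 7 were higher and 0 lower (7 and 0 also adjusted over the list alone; median 0.33; camera adjusted p = 4.55e-04, and adjusted p = 0.0794 with an estimated correlation). Among them the atrial light chain genes Myl7 and Myl4 rose by 0.94 and 0.33 on the log2 scale. Tbx5 rose from 28.3 ± 1.49 to 48.0 ± 0.778 TPM (log2 fold change 0.73, SE 0.12, adjusted p = 1.75e-04), and the natriuretic peptide gene Nppa rose from 4500 ± 606 to 9750 ± 730 TPM (log2 fold change 1.02, adjusted p = 3.00e-04). Hand1 (-0.11, adjusted p = 0.423), Gja5 (-0.22, adjusted p = 0.465), Bmp10 (0.18, adjusted p = 0.444) and Myh6 (-0.02, adjusted p = 0.877) were not called. The compact myocardium list as a whole was not called either, with 4 of 9 members higher and 2 lower, the same counts adjusted over the list alone (camera adjusted p = 0.555).

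The largest increases among abundant genes of the left ventricle included the ryanodine receptor gene Ryr3 (log2 fold change 3.42, SE 0.12, adjusted p = 5.17e-12), the atrial myosin-binding protein gene Mybphl (2.96, SE 0.08, adjusted p = 2.48e-13) and the zinc transporter gene Tmem163 (2.88, SE 0.15, adjusted p = 1.45e-09). Mybphl went from 6.79 ± 0.61 to 55.0 ± 2.14 TPM and Tmem163 from 10.4 ± 2.39 to 82.7 ± 3.09 TPM. The secreted protein gene Dkk3 rose from 17.0 ± 1.78 to 93.0 ± 5.44 TPM. The muscle creatine kinase gene Ckm fell 4.67-fold, from 96.2 ± 15.5 to 21.8 ± 2.12 TPM (log2 fold change -2.22, SE 0.13, adjusted p = 3.64e-09). The myoglobin gene Mb fell from 502 ± 49.4 to 174 ± 19.2 TPM (log2 fold change -1.61), and the potassium channel subunit gene Kcne1 from 40.9 ± 1.92 to 11.7 ± 2.27 TPM (-1.93). The water channel gene Aqp4 fell from 3.28 ± 0.529 to 0.559 ± 0.106 TPM (-2.57). The stress-responsive genes Ankrd1 and Adm rose by 1.33 and 1.49 (adjusted p = 2.45e-06 and 5.22e-06).

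**Figure D2:**
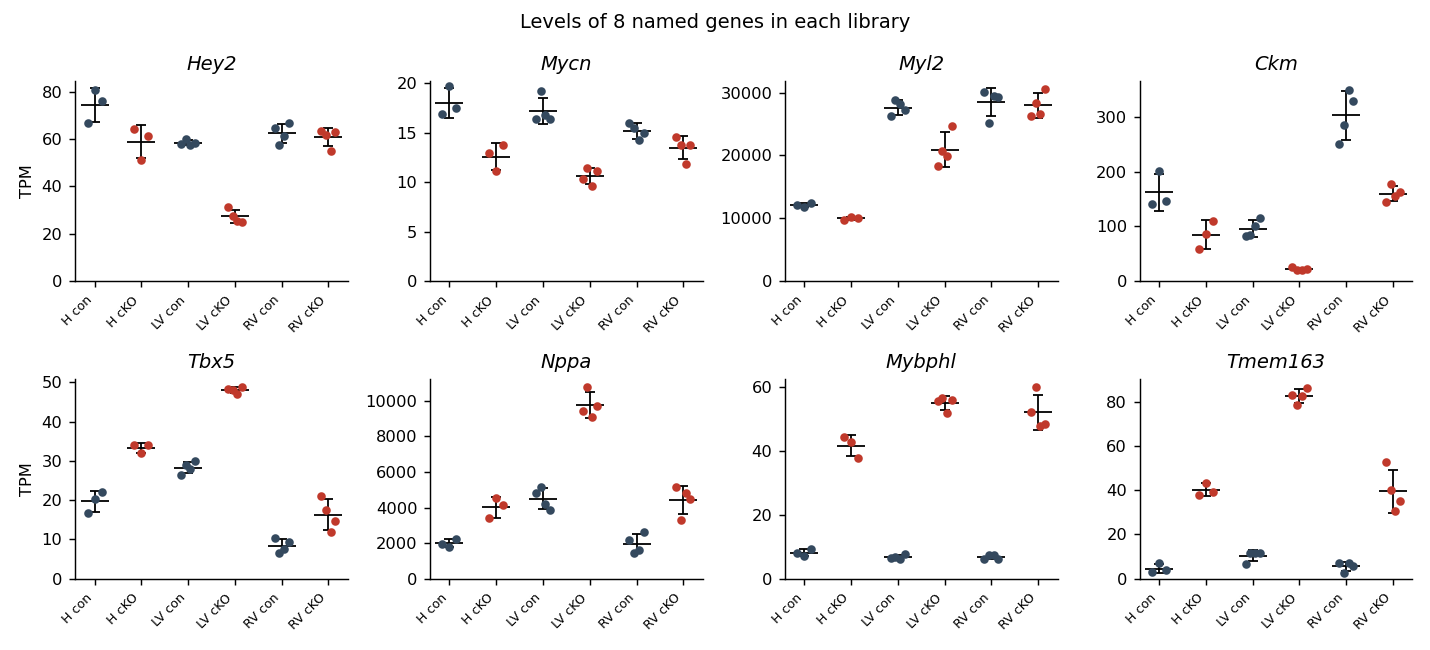
Level in TPM (vertical axis of each panel) of Hey2, Mycn, Myl2, Ckm, Tbx5, Nppa, Mybphl and Tmem163 in each library (dots), with the mean and SD of each group (bars), for control and cKO whole hearts, left ventricles and right ventricles. Hey2 falls from 58.4 to 27.2 TPM in the left ventricle against 62.4 and 60.8 TPM in the right, whereas Mybphl rises to 55.0 and 52.1 TPM in the left and right ventricle.

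Energy metabolism lists were tested in the left ventricle, and their calls were lost with an estimated correlation. Of 34 nuclear genes of oxidative phosphorylation, 33 fell and 1 rose (33 and 1 also adjusted over the list alone), with a median log2 fold change of -0.41 (camera adjusted p = 7.01e-22, and adjusted p = 0.243 with an estimated correlation). Sdha (-0.57), Cyc1 (-0.60) and Cox7a1 (-1.01) were among those that fell. The 1 member that rose was Cox6a2 (0.45, adjusted p = 1.81e-05), singled out here after its values were seen. Of 29 fatty acid oxidation genes, 23 fell (24 adjusted over the list alone) and 0 rose, with a median of -0.49 (camera adjusted p = 4.25e-17, and adjusted p = 0.173 with an estimated correlation). Acadm (-0.65) and Fabp3 (-0.55) were among these, and the mitochondrial coactivator gene Ppargc1a fell by 0.85 (adjusted p = 2.88e-08). Of 25 glycolysis genes, 14 fell and 1 rose (19 and 1 adjusted over the list alone; camera adjusted p = 2.02e-06, and adjusted p = 0.421 with an estimated correlation), Pfkm, Ldhb and Aldoa among those that fell. Of 13 mitochondrially encoded protein genes, 7 fell (8 adjusted over the list alone; median -0.22; camera adjusted p = 0.00695, and adjusted p = 0.541 with an estimated correlation). Mitochondrially encoded genes took 5.34% to 5.91% of reads in the cKO left ventricles and 6.30% to 6.88% in their controls. Brown fat genes, where Prdm16 has a known role, had 5 of 11 lower and 1 higher (7 and 1 adjusted over the list alone; camera adjusted p = 0.00379, and adjusted p = 0.173 with an estimated correlation).

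Lists of cell division genes and cell cycle inhibitors were tested, and their calls were also lost with an estimated correlation. Of 33 proliferation genes, 23 fell and 0 rose (25 lower and 2 higher adjusted over the list alone), with a median log2 fold change of -0.22 (camera adjusted p = 3.80e-09, and adjusted p = 0.421 with an estimated correlation). Mki67 fell by 0.30, Bub1b by 0.42 and Mcm7 by 0.35, whereas the cyclin gene Ccnd2 rose by 0.65 (adjusted p = 1.06e-07). Of 13 cell cycle inhibitors and p53 targets, 7 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.00509, and adjusted p = 0.173 with an estimated correlation), including Cdkn1c (0.43), Cdkn1a (0.41) and Eda2r (0.67). The sarcomere list had 17 of 30 members lower and 5 higher (18 and 6 adjusted over the list alone); its median was -0.17 and its mean 0.03 (camera adjusted p = 0.0182, downward, and adjusted p = 0.679 with an estimated correlation). Markers of some other cell types were higher. Of 10 epicardial markers, 7 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 0.00108, and adjusted p = 0.243 with an estimated correlation), Wt1 (0.52) and Aldh1a2 (0.60) among them. Of 15 endothelial and endocardial markers, 9 rose and 3 fell (10 and 3 adjusted over the list alone; camera adjusted p = 0.0013, and adjusted p = 0.243 with an estimated correlation), with Tek and Npr3 higher by 0.36 and 0.52. Of 33 TGF-beta and BMP pathway genes, 11 rose and 0 fell, the same counts adjusted over the list alone, Id2 (0.64) and Id4 (1.24) among them (camera adjusted p = 1.01e-04, and adjusted p = 0.421 with an estimated correlation). Haemoglobin genes took 1.30% to 3.25% of reads in the cKO and 0.99% to 1.92% in the controls, and the erythroid list was higher in the camera test (median 0.73, adjusted p = 0.0138, and adjusted p = 0.679 with an estimated correlation). Of its 11 members 1 was called, and 0 when adjusted over the list alone.

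The right ventricle comparison asked the same question in the other chamber. In the cKO right ventricle 7 of 13 atrial cardiomyocyte markers were higher, a list call that held with an estimated correlation (adjusted p = 0.00286), and 17 of 29 fatty acid oxidation genes were lower, a call that was lost with it (adjusted p = 0.305). Hey2 was not called. Of 16448 genes, 1696 differed (10.3%), 1007 higher and 689 lower, and 219 changed by more than 1 on the log2 scale (159 higher, 60 lower). Without right ventricle control 2, 2418 genes differed, 1233 higher and 1185 lower. The 8 libraries of the right ventricle alone gave 1052 genes, and length-scaled counts 831.

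Hey2 was at 60.8 ± 3.96 TPM in the cKO right ventricles and 62.4 ± 4.06 TPM in the controls (log2 fold change -0.04, SE 0.06, adjusted p = 0.732). Mycn had -0.16 (adjusted p = 0.0633, but 0.0272 without right ventricle control 2 and 0.0443 without cKO 1), and Myl2 had -0.12 (adjusted p = 0.387, and 0.00415 at -0.22 without that library). The largest increases included Tmem163 (3.12, SE 0.17, adjusted p = 2.99e-09), Mybphl (2.94, SE 0.08, adjusted p = 2.25e-13), the exchange factor gene Tiam2 (2.60) and Ryr3 (2.50). Tmem163 went from 5.62 ± 2.09 to 39.5 ± 9.62 TPM and Mybphl from 6.77 ± 0.743 to 52.1 ± 5.56 TPM. Nppa rose from 1970 ± 538 to 4430 ± 790 TPM and Tbx5 from 8.38 ± 1.66 to 16.3 ± 3.9 TPM. Among the decreases were the fast skeletal troponin gene Tnni2, from 81.6 ± 11.1 to 26.5 ± 2.03 TPM (log2 fold change -1.59, SE 0.15, adjusted p = 2.87e-06), Kcne1 (-1.18) and the mitochondrial regulator gene Perm1 (-1.27).

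Of 13 atrial cardiomyocyte markers, 7 rose and 0 fell in the right ventricle, the same counts adjusted over the list alone, with a median of 0.70 (camera adjusted p = 6.28e-08, and adjusted p = 0.00286 with an estimated correlation). This was the 1 list call in these 6 comparisons that held with an estimated correlation. Kcnk3 (1.29), Kcnj5 (0.76) and Myl7 (0.88) were among the members that rose. Of 29 fatty acid oxidation genes, 17 fell and 1 rose (19 and 1 adjusted over the list alone), with a median of -0.23 (camera adjusted p = 4.15e-11, and adjusted p = 0.305 with an estimated correlation), Acsl1 (-0.59) and Acadm (-0.44) among those that fell. Of 34 oxidative phosphorylation genes, 6 fell and 1 rose (12 and 1 adjusted over the list alone; median -0.14; camera adjusted p = 2.48e-07, and adjusted p = 0.745 with an estimated correlation). Without right ventricle control 2, 33 of the 34 fell at a median of -0.22. Of 33 proliferation genes, 4 fell (9 adjusted over the list alone; camera adjusted p = 1.44e-05, and adjusted p = 0.745 with an estimated correlation), and 19 fell without that library. Of 9 ventricular cardiomyocyte markers, 2 were higher and 1 lower (2 and 3 adjusted over the list alone; camera adjusted p = 0.98). Without right ventricle control 2, 2 were higher and 4 lower (median -0.10; camera adjusted p = 0.18). Of 13 cell cycle inhibitors and p53 targets, 4 rose (6 adjusted over the list alone; camera adjusted p = 0.00101, and adjusted p = 0.128 with an estimated correlation), Cdkn1c by 0.45, whereas Ccnd2 rose by 0.96 (adjusted p = 2.34e-09). Haemoglobin genes took 1.13% to 2.24% of reads in the cKO and 0.51% to 1.24% in the controls, with 5 of 11 erythroid markers higher (9 adjusted over the list alone, and 1 without right ventricle control 2; camera adjusted p = 1.44e-05, and adjusted p = 0.722 with an estimated correlation). Mitochondrially encoded genes took 5.65% to 6.46% of reads in the cKO and 6.65% to 7.38% in the controls.

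A test of the difference between the ventricles asked which cKO effects were specific to a side. Hey2 and Mycn fell by more in the left ventricle. The oxidative phosphorylation, fatty acid oxidation and ventricular cardiomyocyte lists also had lower fold changes on the left, with 4 of 34, 5 of 29 and 3 of 9 members called, and these list calls were lost with an estimated correlation (adjusted p = 0.346, 0.346 and 0.0856). The rises of Tbx5 (difference -0.17, adjusted p = 0.724) and Nppa (-0.14, adjusted p = 0.861) were not shown to differ. Of 16448 genes, 236 differed in their cKO effect (1.43%), 160 with the lower and 76 with the higher fold change in the left ventricle. Without right ventricle control 2 there were 358. Length-scaled counts gave 64, voom 414 and DESeq2 454. Leaving out left ventricle cKO 2, 3 or 4 gave 135, 125 or 157, and left ventricle control 2, 3 or 4 gave 146, 151 or 137. Leaving out right ventricle cKO 2 or 4 gave 138 or 136.

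Hey2 had a left minus right difference of -1.10 in its log2 fold change (SE 0.08, adjusted p = 5.04e-06) and Mycn -0.65 (SE 0.08, adjusted p = 6.54e-04). Ckm fell by 2.22 in the left and by 0.92 in the right ventricle (difference -1.30, SE 0.17, adjusted p = 8.93e-04). Aqp4 (-1.58) and the muscle protease gene Ky (-1.36) also had lower fold changes in the left ventricle. The ectonucleotidase gene Nt5e rose by 1.90 in the left ventricle against 0.12 in the right (difference 1.78, SE 0.30, adjusted p = 0.00657), and the growth factor gene Pdgfc by 1.5 against 0.04 (1.46, adjusted p = 0.00276). Kcnj8 (1.49) and Lrp8 (1.56) also had higher fold changes in the left ventricle. Myl2 (-0.40, adjusted p = 0.0918) and Myh7 (-0.28, adjusted p = 0.0859) were not called, though Myl2 was without right ventricle control 1 (adjusted p = 0.0414) or 2 (0.0222), and Myh7 without right ventricle control 4 (0.0496). Of 34 oxidative phosphorylation genes, 4 had a lower fold change on the left (30 adjusted over the list alone, and 16 without right ventricle control 2), with a median difference of -0.28 (camera adjusted p = 7.87e-24, and adjusted p = 0.346 with an estimated correlation). Of 9 ventricular cardiomyocyte markers, 3 did (7 adjusted over the list alone; median -0.28; camera adjusted p = 9.45e-10, and adjusted p = 0.0856 with an estimated correlation), among them Irx4 (-0.53). Of 29 fatty acid oxidation genes, 5 did (12 adjusted over the list alone; median -0.21; camera adjusted p = 3.16e-11, and adjusted p = 0.346 with an estimated correlation). The atrial marker list had a median difference of -0.01 with 0 of 13 members called, also 0 without right ventricle control 2.

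**Figure D3:**
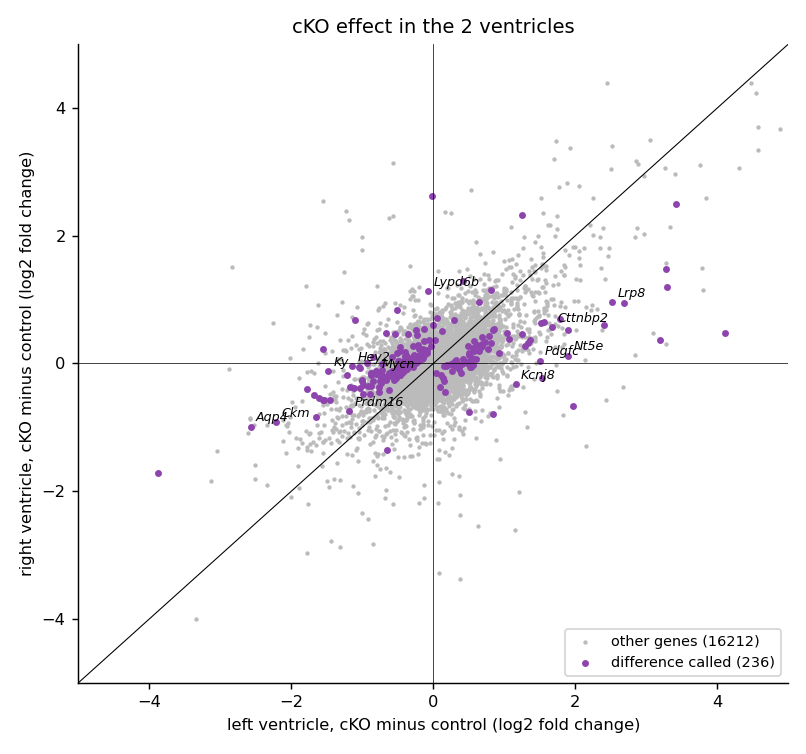
Log2 fold change, cKO over control, of each gene tested in the left ventricle (horizontal axis) and the right ventricle (vertical axis). Purple marks genes whose fold change differed between the ventricles; 22 of 16448 genes lie beyond the axes at 5. Hey2 lies at -1.14 and -0.04, and Ckm at -2.22 and -0.92.

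The whole heart comparison asked which changes are seen without dissection. Of the fixed lists, atrial cardiomyocyte markers were higher, and ventricular cardiomyocyte markers and oxidative phosphorylation genes lower. These calls were lost with an estimated correlation (adjusted p = 0.071, 0.0964 and 0.141). Of 19160 genes, 773 differed, 376 higher and 397 lower, and 116 changed by more than 1 on the log2 scale (89 higher, 27 lower). Without whole heart control 1, 1292 differed. Without cKO 1, 2 or 3 there were 238, 184 or 211, and without control 3 there were 282. Length-scaled counts gave 135 genes, a replicate block 218, voom 1777, DESeq2 1657 and all 22 libraries in one fit 2012. Library totals gave 434 higher and 330 lower, and the fit of 22 libraries 803 higher and 1209 lower.

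Tmem163 rose from 4.50 ± 2.12 to 40.1 ± 2.94 TPM (SD, 3 libraries each; log2 fold change 2.49, SE 0.10, adjusted p = 4.38e-05), Mybphl from 8.13 ± 1.16 to 41.7 ± 3.36 TPM (2.28, adjusted p = 1.04e-04) and Ryr3 from 4.41 ± 1.39 to 25.0 ± 2.31 TPM (2.49, adjusted p = 1.28e-04). Tnni2 (-1.62, SE 0.13, adjusted p = 0.00143) and Mb (-1.21, SE 0.14, adjusted p = 0.00501) fell. Mycn fell by 0.69 (adjusted p = 0.00334), Myl2 by 0.34 (adjusted p = 0.00201) and Myl3 by 0.47 (adjusted p = 0.00113), and Tbx5 rose by 0.68 (adjusted p = 0.00116). Hey2 had a log2 fold change of -0.41 (SE 0.09, adjusted p = 0.0483), a call lost without cKO 1, 2 or 3 or control 2 or 3 (adjusted p = 0.118, 0.115, 0.122, 0.0947 and 0.157). Of 9 ventricular cardiomyocyte markers, 7 fell (7 adjusted over the list alone; camera adjusted p = 9.40e-08, and adjusted p = 0.0964 with an estimated correlation). Of 13 atrial markers, 7 rose and 0 fell (9 and 0 adjusted over the list alone; median 0.58; camera adjusted p = 2.54e-09, and adjusted p = 0.071 with an estimated correlation). Of 34 oxidative phosphorylation genes, 16 fell and 0 rose (33 lower and 1 higher adjusted over the list alone, and 22 lower without whole heart control 1), with a median of -0.30 (camera adjusted p = 1.16e-24, and adjusted p = 0.141 with an estimated correlation). Of 30 fatty acid oxidation genes, 12 fell (23 adjusted over the list alone, and 17 without that library; camera adjusted p = 2.37e-17, and adjusted p = 0.071 with an estimated correlation), Acadm by 0.44. Of 33 proliferation genes, 3 fell (13 adjusted over the list alone, and 5 without that library; camera adjusted p = 1.36e-10, and adjusted p = 0.0813 with an estimated correlation). Mesenchyme and fibroblast markers had 0 of 13 called, 7 higher adjusted over the list alone and 2 higher without whole heart control 1 (median 0.22; camera adjusted p = 1.01e-04, and adjusted p = 0.0975 with an estimated correlation).

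Left and right ventricles were compared within each genotype to ask whether side differences persist in the cKO. Hand1, Gja5 and Tbx5, which mark the left ventricle, were higher on the left in both genotypes. Hey2 and Ckm were lower on the left in both genotypes, and by more in the cKO than in the controls. Mycn had a mean of 17.22 TPM on the left and 15.19 TPM on the right in the controls. In the cKO it had 10.65 and 13.48 TPM, so the direction of its side difference changed. In the controls 3462 of 16448 genes differed between sides (21%; 1483 higher on the left), and 4482 without right ventricle control 2. In the cKO 5398 differed (32.8%; 2387 higher on the left). Length-scaled counts gave 1691 and 3207. The share higher on the left was 42.8% and 44.2% with TMM factors and 63.9% and 66.2% with library totals, which moved the median of all genes from 0.00423 to 0.0581 in the controls and from 0.0166 to 0.0935 in the cKO.

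Gja5, a gap junction gene of the trabecular and conducting myocardium, was at 277 ± 24.5 TPM in the left and 54.7 ± 14.6 TPM in the right control ventricles (log2 2.32, SE 0.21, adjusted p = 1.34e-06), and its difference in the cKO was 2.42 (adjusted p = 4.50e-07). Hand1 differed by 2.07 in the controls and 2.14 in the cKO (adjusted p = 1.21e-09 and 7.52e-10), and Tbx5 by 1.62 and 1.45. Tnni2 was lower on the left by -2.36 in the controls and -3.29 in the cKO. For Hey2, left versus right ventricle in control hearts differed by -0.18 (adjusted p = 0.0313, and 0.0689 to 0.1 without left ventricle control 1, 3 or 4 or right ventricle control 1, 3 or 4), and in the cKO by -1.29 (SE 0.06, adjusted p = 7.52e-10). Ckm in the cKO was at 21.8 ± 2.12 TPM on the left and 160 ± 14.1 TPM on the right. Of 6 left ventricle identity genes, 5 were higher and 1 lower on the left in both genotypes, the same counts adjusted over the list alone (camera adjusted p = 1.22e-05 in the controls and 0.00188 in the cKO, and adjusted p = 0.326 and 0.202 with an estimated correlation). Oxidative phosphorylation genes were lower on the left in 27 of 34 cases in the controls (32 adjusted over the list alone; median -0.23) and in 34 of 34 in the cKO (34 adjusted over the list alone; median -0.54), with camera adjusted p = 2.87e-14 and 1.66e-26, and adjusted p = 0.547 and 0.202 with an estimated correlation.

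Genes that differ between the control ventricles were then followed in the left ventricle of the cKO, with controls 1 and 2 defining the genes and controls 3 and 4 entering the test. The 22 right-enriched genes had a median log2 fold change of -0.53, with 10 called lower and 5 higher, and in the right ventricle of the cKO a median of -0.178, with 6 lower and 2 higher. The 31 left-enriched genes had a median of -0.01 in the left ventricle, with 11 called lower and 8 higher. In 5 data sets simulated without a cKO effect, left ventricle medians of genes defined in this way averaged 0.00367 (right-enriched) and 0.00357 (left-enriched). These data sets drew each gene independently and had no library set apart like right ventricle control 2. Their averages therefore do not show how far chance can move the median of so few genes. With all 4 controls in both steps, 1404 right-enriched genes had a median of -0.0697 in the left and -0.0487 in the right ventricle. The same controls define and test these genes, and simulated data without a cKO effect gave 0.0213 and -0.0217. In the right ventricle 62.6% of these genes were lower, against 61.4% in the simulated data. With controls 3 and 4 defining the genes and controls 1 and 2 in the test, right ventricle control 2 left the definition and entered the test. No data were simulated for this split. Its 1422 right-enriched genes had a median of -0.16 in the left ventricle, with 517 lower and 158 higher. In the right ventricle they had a median of -0.0307, with 56 lower and 117 higher, so more were called higher there than lower, unlike in the other split. Right ventricle control 2 is among the controls behind these right ventricle values. The contrast between the splits therefore cannot be told apart from an effect of that library. The 1123 left-enriched genes of that split had a median of 0.09 in the left ventricle, with 94 lower and 187 higher, so the sign for left-enriched genes differed between the splits.

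The cKO effect was shared in part between the tissues. The whole heart and left ventricle comparisons, which share no library, had 330 genes higher in both (46 expected from independent calls), 372 lower in both (53.5 expected) and 0 called in opposite directions. The whole heart and right ventricle had 281 higher in both (23 expected), 209 lower in both (16.8 expected) and 0 opposite. The left and right ventricle, whose libraries may come from the same hearts, had 760 higher in both (123 expected), 534 lower in both (92.1 expected) and 9 opposite. Across genes, which are not independent replicates, Pearson's r between the log2 fold changes was 0.534 for the whole heart and left ventricle, 0.424 for the whole heart and right ventricle, and 0.52 for the left and right ventricle, and Spearman's rho was 0.521, 0.345 and 0.52. Tmem163, Mybphl and Ryr3 rose and Prdm16 fell in each of the 3 tissues.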

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

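The tests of depth for whole heart control 1, of the sarcomere genes for the cardiomyocyte share, and the 3 tests for right ventricle control 2 given here were chosen after the result was seen. The other tests of this part, and its splits of the libraries, were chosen before.

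Whole heart control 1 lay far from the other 5 whole hearts on the first principal component, at 140.3 against -33 to -19.3. Lower depth (38590751 reads against 51541253 or more) is argued against, since at a common depth of 14486402 reads it had 18966 genes with a read, against 22483 to 23519 in the other 21 libraries. Few distinct RNA fragments behind the reads may be the source: 394 of its 16336 genes with at least 20 reads expected had none, against 76 to 88 genes in the other 5 whole hearts. Without it 1292 rather than 773 genes were called in the whole heart. No biological explanation was tested, and the design names none for a single control.

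Right ventricle control 2 was set apart from the other 3 right ventricle controls in 10 of the 20 groups in which a single library lay far from the rest; chance gives about 1 in 20 of the 208 groups examined. Few distinct fragments were not shown as the source, since it had 23027 genes at the common depth, against at most 22778 in the other 3. This count cannot exclude them, because genes that were higher in this library may raise it. An earlier form of this test, 36 genes without a read against 20 to 26, decided nothing. A left ventricle under a right ventricle label is argued against by Hand1, at 12.2 TPM against 38.9 or more in the left ventricle controls and at most 7.35 in the other 3. More cushion and valve mesenchyme in the dissected tissue was not shown as the source. The fixed mesenchyme list lay 1.587 higher on the log2 scale than in the other 3, in 13 of 13 members, and at most 0.319 higher in the other 15 ventricle libraries, but this list was itself among the groups that set the library apart, so the test cannot tell. Postn was at 266 against 44.6 ± 2.83 TPM, Col3a1 at 609 against 256 ± 7.17 TPM and Sox9 at 9.41 against 1.11 ± 0.116 TPM, while all 13 members were also at 1 TPM or more in the other 3 and 6 belong to another list.

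Oxidative phosphorylation genes were lower in the left ventricle of the cKO, and by more there than in the right ventricle, though both list calls were lost with an estimated correlation (adjusted p = 0.243 and 0.346). The scaling between libraries is argued against, since the highest median over TMM, RLE and library totals was -0.391, with 33 of 34 members lower under each. Right ventricle control 2 is argued against as the whole cause of the difference between ventricles, since without it the median was -0.202 with 34 of 34 members lower. The median shrank from -0.28, and it passed the bound set beforehand, -0.2, by less than its SE over members, 0.0175. That SE takes genes of the same libraries as replicates and does not measure the spread between libraries. The conclusion rests on the distance of the median from -0.1, the value set for that library as the cause, and no spread between libraries was computed for that distance. A lower share of cardiomyocytes cannot be told apart from lower levels within them: 4 of the 10 most abundant sarcomere genes lay above the median of the list by over 2 standard errors, their own median was -0.37 against -0.41, and epicardial and endothelial markers were higher. An effect of Prdm16 on these genes, the difference the design names, stays open beside it.

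Other splits of the same libraries were counted for each comparison. The real split gave 4216 genes in the left ventricle against at most 1 in the others of 35 splits, 1696 in the right ventricle against at most 292 in the others of 35, and 236 for the difference between ventricles against at most 1 in the others of 60 splits drawn. For left against right it gave 3462 genes in the controls and 5398 in the cKO, against at most 1155 and 28 in the others of 35 splits each. In each of these 5 comparisons 1 split, the real one, gave as many genes. That is a share under 0.05 if the libraries are independent of each other, which argues against chance, though so few splits cannot exclude it. The series speaks of pairs, and the labels do not say whether equal numbers mark litters or hearts. If they did, swaps within 4 pairs would be too few for a share under 0.05 in the comparisons of 4 with 4 libraries, and the splits drawn for the difference between ventricles did not keep such pairs together. In the whole heart the real split gave 773 genes and the highest of the others 7, but 10 splits are too few for a share under 0.05.

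The cKO effect differed between the left and right ventricle, by the test of that difference, for 236 genes. Named ones with a lower fold change on the left were Aqp4 (-1.58), Ky (-1.36), Ckm (-1.30), Lypd6b (-1.20), Hey2 (-1.10), Mycn (-0.65) and Prdm16 itself (-0.44, SE 0.10, adjusted p = 0.0404). The call of Prdm16 held without left ventricle control 1 or 3 or right ventricle control 4 (adjusted p = 0.0246, 0.0461 and 0.0163) and was lost without each of the other 13 ventricle libraries (adjusted p = 0.0503 to 0.0922). Those with a higher one were Nt5e (1.78), Lrp8 (1.56), Kcnj8 (1.49), Pdgfc (1.46) and Cttnbp2 (1.10). Lypd6b fell short of the threshold without left ventricle cKO 2 (adjusted p = 0.0525) and without left ventricle control 4 (adjusted p = 0.0508). Lists with a lower fold change on the left, by median, were oxidative phosphorylation (-0.28), ventricular cardiomyocyte markers (-0.28), brown fat (-0.28), fatty acid oxidation (-0.21), glycolysis (-0.15), sarcomere (-0.15), calcium handling and ion channels (-0.15) and proliferation (-0.11). Lists with a higher one were mesenchyme (0.43), TGF-beta and BMP (0.25), epicardial (0.25), extracellular matrix (0.12) and endothelial markers (0.09). Of these 13 list calls 0 held with an estimated correlation, the smallest adjusted p being 0.0856, and the mesenchyme, extracellular matrix and TGF-beta lists lost their call without right ventricle control 2 (adjusted p = 0.868, 0.868 and 0.0636). Without that library each list lower on the left kept its call with the preset correlation but had a median of smaller size, glycolysis -0.0918 and proliferation -0.0636 among them.

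Single libraries lay far from the other 3 of their group for some cardiac genes. Of 208 groups examined 20 had such a library, which was right ventricle control 2 in 10 of them. Chance gives about 1 in 20, so the cases of the other libraries are about as many as chance gives. Right ventricle control 2 had Hand1 at 12.2 TPM (others 6.38 to 7.35), Hand2 at 51.4 TPM (34.2 to 35.1) and Mecom at 22 TPM (5.43 to 7.12). Left ventricle control 3 had Gja5 at 240 TPM (285 to 291) and Mecom at 8.92 TPM (5.85 to 6.15), and left ventricle control 2 had Mycn at 19.2 TPM (16.4 to 16.8). Left ventricle cKO 1 had Hand1 at 51.2 TPM (35.7 to 36.9), right ventricle cKO 1 had Myh6 at 534 TPM (679 to 682) and right ventricle control 1 had Myh7 at 4356 TPM (4132 to 4153). By the mean log2 TPM of a list, right ventricle control 2 also lay apart for right ventricle and outflow tract genes (2.39, others 1.63 to 1.66), neuronal genes (1.29, 1.05 to 1.09), TGF-beta and BMP genes (4.41, 3.73 to 3.79), neuregulin and ephrin genes (3.24, 2.86 to 2.92), extracellular matrix genes (6.17, 5.08 to 5.18), mesenchyme markers (5.82, 4.19 to 4.36) and smooth muscle markers (4.93, 4.12 to 4.17). Left ventricle control 3 did so for autonomic and neural crest markers (0.836, others 0.893 to 0.901) and fatty acid oxidation genes (5.44, 5.38 to 5.39), left ventricle control 1 for neuregulin and ephrin genes (3.14, 2.95 to 2.98), and left ventricle cKO 1 for smooth muscle markers (4.24, 4.12 to 4.14). Transcripts without a match in the annotation held at most 0.204% of the reads of a library and entered no comparison.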

How the results depend on the processing

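The voom weights and the list tests without the libraries that stand apart were chosen after the data were seen. Over the alternatives, named genes kept direction and side of the threshold in 16298 cases, passed it in 410, fell short in 804 and reversed in 4, and lists did so in 601, 40, 106 and 1.

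A threshold of 1 on the absolute log2 fold change left 116 genes in the whole heart, 400 in the left and 219 in the right ventricle, 35 for the difference between ventricles, and 263 and 396 for left against right in the controls and the cKO. Length-scaled counts gave 135, 2683, 831, 64, 1691 and 3207 genes in that order, with a biological coefficient of variation of 0.267 in the whole heart and 0.165 in the ventricles against 0.184 and 0.0929; the cause was not tested. With them Ccnd2 reversed in the difference between ventricles (0.075) and in left against right in the cKO (0.007), and Erbb4 (0.031) and Uchl1 (0.139) in left against right in the controls. Ccnd2 in the whole heart had 0.03 (adjusted p = 0.98) with length-scaled counts against 0.82 to 0.87 in the other alternatives.

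Voom with quality weights called 1777 genes in the whole heart (772 of the 773 among them) and 414 for the difference between ventricles (231 of the 236), and DESeq2 called 1657 (766 shared) and 454 (231 shared). In the voom fit whole heart control 1 had a weight of 0.193 against 0.873 to 1.78 in the other 5. All 22 libraries in one fit gave 2012 genes in the whole heart (718 shared). The 8 libraries of the right ventricle alone gave 1052. On deposited TPM, as log2 of TPM plus 1 with limma, for Prdm16, whole heart cKO versus control gave a difference of -0.82 (adjusted p = 0.139, over its alternatives 2.02e-19 to 0.139). On the same scale, for Prdm16, right ventricle cKO versus control gave -0.50 (adjusted p = 0.0984, over its alternatives 4.87e-18 to 0.0984). The added 1 makes differences smaller at these levels, so they are not log2 fold changes of TPM. Why the calls were lost was not tested.

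With the replicate number as a replicate block, 218 genes were called in the whole heart (216 shared), 4166 in the left (3849 shared) and 1586 in the right ventricle (1425 shared). With genotype and number as the block, 196 were called for the difference between ventricles (155 shared), and 3548 (3124 shared) and 5468 (5024 shared) for left against right in the controls and the cKO. In the fits of 1 tissue, cKO and control libraries of the same number had residuals correlated across genes at -0.116 to 0.104, and those of the same ventricle at -0.008 to 0.131 in the fit of all ventricles. In that fit, left and right ventricles of the same number had 0.237, 0.053, 0.142 and 0.178 in the cKO and 0.094, -0.115, 0.022 and 0.069 in the controls. In the cKO each of these 8 libraries correlated best with its own number on the other side, which is a hint of pairs from the data, not from the design; in the controls this was not so.

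Leaving out 1 library at a time gave 184 to 1292 genes in the whole heart: 238, 184 and 211 without cKO 1, 2 and 3, 1292 without control 1 and 282 without control 3. It gave 3539 to 3863 in the left and 1290 to 2418 in the right ventricle, and 2583 to 4482 and 4489 to 5091 for left against right in the controls and the cKO. For the difference between ventricles it gave 125 to 358: 135, 125 and 157 without left ventricle cKO 2, 3 and 4, 146, 151 and 137 without left ventricle control 2, 3 and 4, 138 and 136 without right ventricle cKO 2 and 4, and 358 without right ventricle control 2. The call of Hey2 in the whole heart was lost with library totals (adjusted p = 0.0567), length-scaled counts (0.193), the replicate block (0.155) and in 5 of the 6 fits that leave out a library. The call of Prdm16 in the difference between ventricles was lost with library totals (adjusted p = 0.0526), length-scaled counts (adjusted p = 0.81) and all 22 libraries in one fit (adjusted p = 0.0715).

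With an estimated correlation camera called 1 list in the right ventricle and 0 in each of the other 5 comparisons. Another list test, fry, called 14 in the whole heart and 17 in the left ventricle, against 14 in each with the preset correlation (12 shared in each). It called 6 in the right ventricle against 11 (5 shared) and 5 for the difference between ventricles against 13 (4 shared). For left against right it called 9 in the controls against 11 (8 shared) and 19 in the cKO against 13 (11 shared). Without right ventricle control 2 the mesenchyme list reversed in the difference between ventricles (adjusted p = 0.868, median -0.01). Left-enriched genes had a median of 0.0871 in the left ventricle cKO when controls 3 and 4 defined them, against -0.01. A sex term was not run, since all libraries looked like 1 sex. At 0.5 on the log2 scale, 40% of simulated changes were called in the whole heart and 69% in the left ventricle.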

Other observations

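The tests of the lists and genes in this part are those of the comparisons above. Nppb, a natriuretic peptide gene induced by wall stress, rose by 1.10 on the log2 scale in the left ventricle of the cKO (SE 0.18, adjusted p = 2.75e-04) and had 0.12 in the right (adjusted p = 0.763). The difference between the ventricles was 0.99 (adjusted p = 0.0671), so it was not shown to differ. The cardiac stress list as a whole had 6 of 11 members higher and 3 lower in the left ventricle, the same counts adjusted over the list alone (median 0.57; camera adjusted p = 0.116). Hypoxia response genes had 4 of 16 higher and 3 lower (4 and 4 adjusted over the list alone; camera adjusted p = 0.928), and Notch pathway genes 3 of 18 higher and 4 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.476).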
